A study of Mus musculus with 18 samples.

How the data were processed

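Polyadenylated RNA of mouse dorsal root ganglion neurons was measured in 18 libraries, 6 each from control cultures, cultures 6 h after compression and cultures 24 h after it. Per the labels' protocols, 8 replicates gave 24 extracts, those with a RIN above 9 were sequenced, and reads were paired and 151 bp long. Per the submitters' processing notes, BWA, featureCounts and DESeq2 were used, without versions, and the genome builds GRCm39 and mm10 are both named without their roles. The deposited values are signal in normalized counts, made by the authors from read counts per Ensembl transcript divided by 1 size factor per library (0.937 to 1.09). There are 2 tables of 278375 transcripts and 12 libraries, of which 1 holds 24 h and control libraries and the other 24 h and 6 h libraries.

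Whole reads were recovered for 100% of values at a tolerance of 1e-06, and the 6 libraries in both tables differed by 0 reads, so the tables were joined. Total reads were 18759966 to 21740631 per library. No column was left without a sample. Transcripts were named and summed to genes by GENCODE M21, which matched 137161 (49.3%) in 52174 genes, and unmatched transcripts held 2.88% to 11.1% of reads. Coordinates are not given because the build is not certain. A gene value is the sum of reads assigned to 1 transcript. Reads that overlap several transcripts may be left out, since Gapdh (13 transcripts) and Actb (9) had mean normalized counts of only 60.8 and 718. Tuba1a and Nefl (1 each) had 113397 and 93296, against 183 for Prph (4) and 0.423 for Mpz (4), though Stmn2 (4) had 41017. Mpz, a Schwann cell marker, was thus below the count filter. Over protein-coding genes the median count rose with the number of transcripts, from 1.84 with 1 to 39.6 with 10 or more. That trend cannot decide, since it does not hold the expression of the genes fixed. The counting settings are not stated, so such a loss of reads is not certain. Values of near-identical genes are uncertain too, because the handling of shared reads is not known.

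Comparisons were 24 h with control, 24 h with 6 h and 6 h with control, the first 2 on the authors' scaling within 1 table and the third on joined reads with median-of-ratios factors. Group means of the same libraries therefore differ slightly between comparisons. Genes with a normalized count of at least 10 in at least 6 libraries were tested with limma 3.58.1 (trend, two-sided) on log2(normalized count + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 46 gene lists fixed before the data were examined, 43 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. Erythroid, skeletal muscle and sex-linked genes were too few. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

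Genes were named by a rule fixed before the data were examined: among genes past the threshold with a mean of at least 50 in the higher group, the 12 higher and 12 lower with the largest log2 fold change, or the 10 with the smallest p where fewer than 10 passed, and up to 4 members per list. List members were those past the threshold with the smallest p, the 2 with the smallest p where a list passed and no member did, and those with the highest mean in lists of other cell types, nuclear-retained RNAs and sex-linked genes. Genes whose symbols mark them as predicted or as pseudogenes (Gm with digits, Rik, -ps) were counted but not named. Cxcl11 and Rps4l, which the annotation types as pseudogenes, have other symbols and were named. Not every gene the rule takes is printed.

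Alternatives were other pseudocounts, filters and scalings, all libraries in 1 fit, a replicate block, library quality weights, edgeR, DESeq2 and leaving out each library. Added after the data were seen were single transcripts, protein-coding genes alone, leaving out 4 libraries that lay apart on the first principal component, covariates for Schwann cell and fibroblast markers, a length correction, a split of the controls with paired 6 h libraries, a split of calls without shared replicate numbers and further settings of the list tests. The procedure was tested on simulated data with added changes. Labels of the groups were also split at random, 100 splits per comparison. Closest replicates of a group differed by more than counting error (chi-square per degree of freedom of 5.14 or more), so no library was a copy of another in its group. Libraries of different groups were not compared in this way.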

Results

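Polyadenylated RNA was sequenced from primary sensory neurons of mouse dorsal root ganglia, taken from C57BL/6J pups at postnatal day 3. The neurons grew in compartmented microfluidic chambers on a stretched silicone (PDMS) film, with nerve growth factor and with AraC, a drug that kills dividing cells. Compression was applied by letting the film go from its stretched to its resting position over 20 cycles at 5% strain. There were 3 groups of 6 libraries: control cultures kept on the stretched film without cycles, cultures extracted 6 h after the cycles (6 h) and cultures extracted 24 h after them (24 h). Replicates are numbered 1, 2, 3, 4, 7 and 8 in each group. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. They also give no extraction time for the controls. The libraries held 18759966 to 21740631 assigned reads, with a median of 19981449.5. Values below are normalized counts per gene as mean ± SD (n = 6 libraries per group), and log2 fold changes are on the log2(normalized count + 1) scale ± SE with adjusted p from limma.

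The first principal component of 16346 genes held 23.8% of the variance and the second 12.1%. All 6 24 h libraries scored between 10.2 and 43.2 on the first component, above each of the other 12 libraries, of which control replicate 1 was the highest at 6.04. Control replicates 2 and 3 (-52.3 and -37.2) and 6 h replicates 2 and 3 (-50.5 and -30.3) lay farthest from the 24 h libraries.

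**Figure D1:**
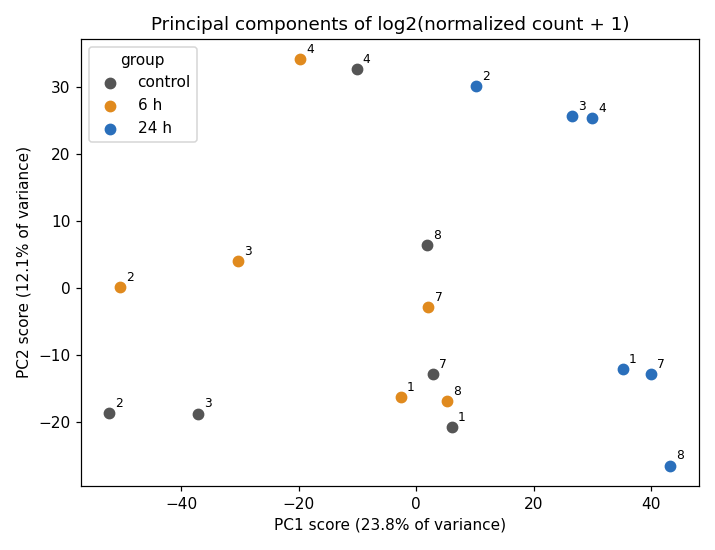
Scores of the 18 libraries on the first and second principal components of log2(normalized count + 1), with the share of variance on each axis. Each point is a library, coloured by group and marked with its replicate number, and the 24 h libraries lie at the right, between 10.2 and 43.2 on the first component.

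The comparison of 24 h with control asked which transcripts differed a day after the compression cycles. At 24 h, transcripts of the itch and pain receptors Mrgprd and Mrgpra3 were higher, as were those of Pmaip1 and Bbc3, which encode pro-apoptotic BH3-only proteins, the activity-induced transcription factor Egr1 and the prostaglandin synthase Ptgs2. The haemoglobin genes Hbb-bt and Hba-a1, the T cell receptor constant region Trbc2 and the Schwann cell receptor Erbb3 were lower. Mrgprd went from 1091 ± 566 in control to 3104 ± 1060.1 (log2 fold change 1.60 ± 0.31, adjusted p = 0.00829), and Pmaip1 from 23.8 ± 8.12 to 93.2 ± 8.01 (2.00 ± 0.22, 0.000218). Hbb-bt went from 679 ± 424 to 53.2 ± 20.3 (-3.53 ± 0.35, 0.000152). For each of these 3 genes, 6 of 6 24 h libraries lay on the same side of the control mean.

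Of 15647 genes tested, 1033 passed an adjusted p of 0.05, 522 higher and 511 lower at 24 h, and 170 and 95 of these differed by more than 2-fold. Among named genes with a mean of at least 50 in the higher group, the largest increases were in Pnliprp2, a pancreatic lipase-related gene (12.4 ± 11.8 to 82 ± 42.4, log2 fold change 3.01 ± 0.57), the homeobox gene Nkx2-9 (8.55 ± 6.81 to 57.8 ± 12.6, 3.00 ± 0.46) and Pdk4, a kinase that inhibits pyruvate dehydrogenase (90.3 ± 48.1 to 504 ± 143, 2.83 ± 0.52). The transcription factor Sp9 (2.78 ± 0.35), Cxcl11, a chemokine gene that the annotation types as a polymorphic pseudogene (2.42 ± 0.54), the muscarinic receptor Chrm1 (2.40 ± 0.32), the neuropeptide FF receptor Npffr1 (2.26 ± 0.42) and Clca2 (2.22 ± 0.35) were higher too. Mrgpra2b (2.42 ± 0.56), Hist1h1b (2.40 ± 0.68) and H2-Q6 (2.23 ± 0.61) were also higher, and each belongs to a family of near-identical genes. Among the genes with large decreases were Sh2d1b1 (198 ± 179 to 17.3 ± 4.95, -3.06 ± 0.42), Hba-a1 (-2.99 ± 0.32), Hba-a2 (-2.82 ± 0.35), Dpm3 (-2.35 ± 0.66), Trbc2 (426 ± 188 to 87.2 ± 30.7, -2.24 ± 0.29) and Trbc1 (-1.90 ± 0.30). The epithelial genes Tmprss11b (-2.23 ± 0.44), Krt6b (-2.16 ± 0.44) and Dmkn (-1.78 ± 0.26), the neuropeptide Nmu (-2.02 ± 0.35) and Shisal2a (-1.99 ± 0.37) were lower too. Reads of the Hba, Trbc, H2-Q, histone and Mrgpr genes can be shared among copies, so the value of any single copy is uncertain. Polyadenylated RNA was sequenced, so the Hist1h1b count need not follow its transcripts without a poly(A) tail. The adjusted p of these 22 genes lay between 0.000218 and 0.0453. Of 12 fits that each left out 1 library, calls above ended in 8 for Dpm3 and Hist1h1b, 6 for H2-Q6 and 1 for Mrgpra2b.

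**Figure D2:**
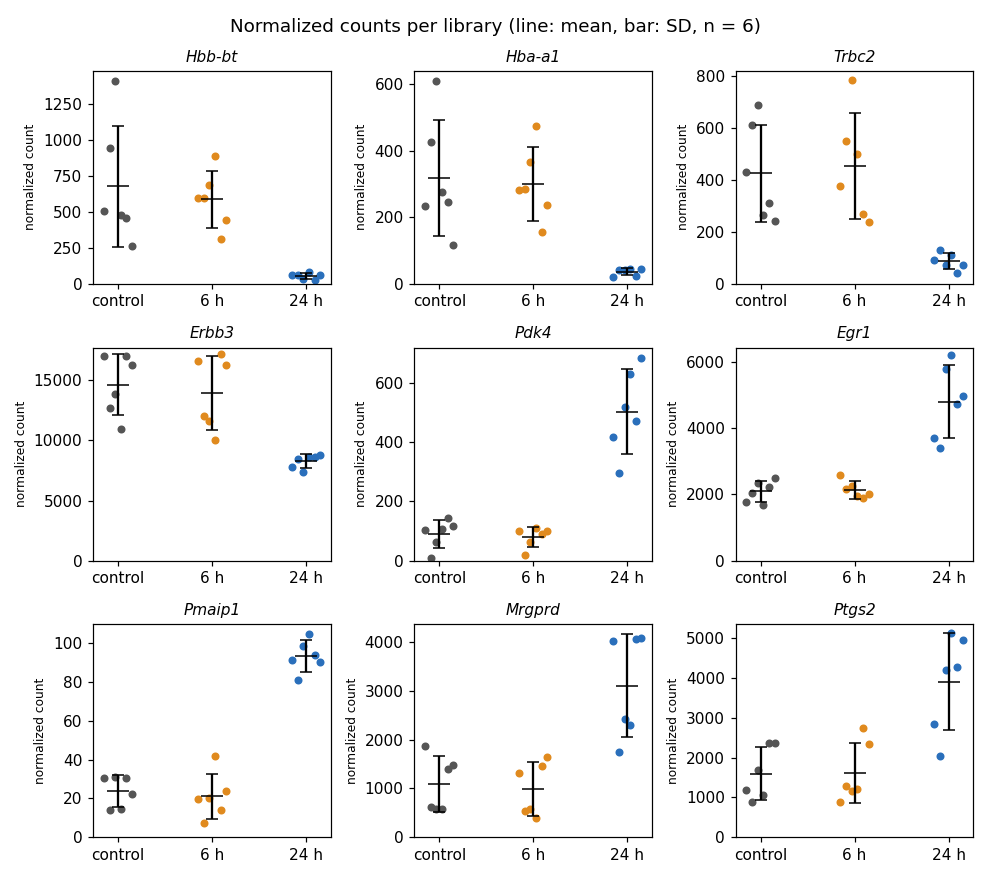
Normalized counts of 9 genes in each library of the 3 groups. Each point is a library, the horizontal line is the group mean and the bar is the SD (n = 6), with Hbb-bt at 53.2 ± 20.3 and Pmaip1 at 93.2 ± 8.01 in the 24 h group.

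Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation. Of the 43 lists tested, 8 rose and 2 fell at 24 h, and 0 passed with an estimated correlation. Of 12 measured markers of non-peptidergic nociceptors, the pain and itch fibres, 5 were higher and 0 lower (7 higher when adjusted over the list alone), with a median log2 fold change of 0.87 (adjusted p = 1.87e-05). For these nociceptor markers the adjusted p was 0.381 with an estimated correlation. The 5 higher members were Mrgprb5 (2.84 ± 0.41), Mrgpra3 (31 ± 20.2 to 192 ± 125, 2.53 ± 0.52), Mrgprx1 (1.73 ± 0.48), Mrgprd and the natriuretic peptide Nppb (84.5 ± 27.8 to 238 ± 127, 1.35 ± 0.33). Mrgprb5 was below the count filter, and so not tested, in each of 6 fits without a 24 h library. Of 21 mechanosensitive channels, the acid-sensing channel Asic2 (1649.7 ± 434 to 2729 ± 417, 0.76 ± 0.17) and the cation channels Trpc3 (0.45 ± 0.13) and Trpc1 (0.39 ± 0.11) were higher and 0 lower, or 6 higher adjusted over the list alone (median 0.29, adjusted p = 0.00288). For the mechanosensitive channels the adjusted p was 0.382 with an estimated correlation. Of 41 voltage-gated channel genes, the sodium channel subunit Scn2b (2923 ± 366 to 5018 ± 1323, 0.75 ± 0.15), the potassium channel Kcnc4 (0.46 ± 0.09) and the calcium channel subunit Cacnb1 (0.45 ± 0.11) were higher and Cacna2d3 lower (-0.84 ± 0.21), or 4 and 1 adjusted over the list alone (median 0.25, adjusted p = 0.0172). For the voltage-gated channels the adjusted p was 0.91 with an estimated correlation. Of 32 synaptic release genes, Unc13a (0.54 ± 0.11), Nrxn2 (0.58 ± 0.13), Syt2 (0.53 ± 0.13), Nrxn3 (0.48 ± 0.13) and Pclo (0.71 ± 0.20) were higher and 0 lower, or 6 and 1 adjusted over the list alone (median 0.17, adjusted p = 0.0422). For the synaptic genes the adjusted p was 0.91 with an estimated correlation. Among 12 leave-one-out fits, the number in which a call above ended was 10 for Trpc3, 9 for Nrxn3, Pclo and Trpc1, 8 for Mrgprx1, 7 for Syt2, 6 for Cacnb1, 5 for Nppb and 1 for Cacna2d3.

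Of 25 p53 targets and apoptosis genes, 6 were higher and 0 lower (10 higher adjusted over the list alone), among them Pmaip1, Bbc3 (615 ± 101 to 1051 ± 135, 0.78 ± 0.12), the death receptor Fas (1.99 ± 0.44) and the kinase Plk2 (0.44 ± 0.10), with a median of 0.43 (adjusted p = 2.46e-05). For the p53 list the adjusted p was 0.382 with an estimated correlation. Of 18 immediate early genes, Egr1 (2093 ± 323 to 4805 ± 1113, 1.18 ± 0.15), Btg2 (1.19 ± 0.18) and Junb (0.99 ± 0.18) were higher and the phosphatase Dusp5 lower (-0.75 ± 0.21), with the same numbers, 3 and 1, adjusted over the list alone (median 0.13, adjusted p = 0.0172). For the immediate early list the adjusted p was 0.91 with an estimated correlation. Of 23 inflammatory and NF-kB genes, Ptgs2 (1592 ± 659.6 to 3901 ± 1219, 1.33 ± 0.27), the adhesion molecule Icam1 (1.30 ± 0.26), the cytokine Lif (1.04 ± 0.28) and the NF-kB inhibitor Nfkbia (0.72 ± 0.19) were higher and the chemokine Cxcl12 lower (-1.19 ± 0.25), or 4 and 2 adjusted over the list alone (median 0.53, adjusted p = 0.00619). For the inflammatory list the adjusted p was 0.91 with an estimated correlation. The 28 cell cycle genes had a median of 0.70 (adjusted p = 0.00514) although 0 passed as higher, and the DNA replication helicase subunit Mcm2 was lower (-0.36 ± 0.10), with 0 past adjusted over the list alone. For the cell cycle list the adjusted p was 0.91 with an estimated correlation. Without the 4 libraries apart on the first component, the list calls ended for cell cycle genes (adjusted p = 0.683), inflammatory genes (0.300) and voltage-gated channels (0.0566). The cell cycle list averaged 6.72 and 7.30 log2 units in control replicates 2 and 3, against 8.48 to 8.72 in the other 4 controls and 8.42 to 8.95 at 24 h. Of 18 ER chaperones, Hyou1 was lower (-0.51 ± 0.14), as it was adjusted over the list alone, and the list fell (median -0.11, adjusted p = 0.0453), a call that ended with quantile normalization (adjusted p = 0.0544). For the chaperones the adjusted p was 0.91 with an estimated correlation. Of 12 fits that each left out 1 library, calls above ended in 10 for Mcm2, 9 for Hyou1, 8 for Dusp5 and Lif and 6 for Nfkbia.

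Of 16 Schwann cell markers, 6 were lower and 0 higher, or 9 and 1 adjusted over the list alone (median -0.49, adjusted p = 0.00181). For the Schwann cell list the adjusted p was 0.381 with an estimated correlation. Erbb3 went from 14656 ± 2527 to 8270.1 ± 578 (-0.81 ± 0.11, adjusted p = 0.000881) and the cadherin Cdh19 from 6575 ± 1353 to 4572 ± 397 (-0.50 ± 0.12, 0.0263), while the myelin gene Pmp22 measured 2595 ± 357 and 2440.3 ± 442 (-0.10 ± 0.13, 0.719). Of 11 satellite glia markers, the endothelin receptor Ednrb (-1.61 ± 0.17) and the potassium channel Kcnj10 (-0.69 ± 0.18) were lower and the glutamate transporter Slc1a3 higher (0.84 ± 0.20), and the list did not pass (adjusted p = 0.804). Of 4 measured erythroid genes, the haemoglobin genes Hbb-bt, Hba-a1 and Hba-a2 were lower, and Gypa was at 8.34 ± 6.22 and 13 ± 3.63 (1.00 ± 0.55, adjusted p = 0.306). Lyz2 was higher among 6 macrophage markers (1773 ± 637 to 3959 ± 1460.1, 1.18 ± 0.26, list adjusted p = 0.391), where C1qa measured 399.6 ± 182 and 369 ± 93.4. Notch3 was higher among 6 mural cell markers (1.25 ± 0.23, list adjusted p = 0.253), Cldn5 lower among 7 endothelial markers (-2.06 ± 0.36, list adjusted p = 0.0669) and Olig2 lower among 5 spinal cord cell markers (-1.02 ± 0.26, list adjusted p = 0.722). None of 13 fibroblast markers passed (list adjusted p = 0.577), with Col1a1 at 79313 ± 31457 and 73008 ± 21700.2. Among 12 leave-one-out fits, the number in which a call above ended was 8 for Kcnj10, 5 for Cdh19 and Olig2 and 4 for Slc1a3. Sox10, 1 of the 6 lower Schwann cell markers, was not tested in 6 of these fits, and its call ended in 5 of the other 6. The genes Lif, Pclo, Mrgprx1, Sox10, Ednrb, Slc1a3 and Cldn5 lay outside the rule for named genes and were named after their values were seen.

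Other lists did not pass as lists at 24 h, though single members did. Among axon injury genes (24 measured, adjusted p = 0.72), the arginase Arg1 (448 ± 67.4 to 192 ± 42, -1.23 ± 0.15), Gfra1 and Nts were lower. Among axon guidance genes (33, 0.25), the ephrin Efnb3 (1.31 ± 0.16) and the semaphorin Sema4d (0.85 ± 0.10) were higher and Efna2 and Ephb2 lower. Among growth factor genes (19, 0.159), Igf1 (0.99 ± 0.19) and the receptor Lifr (0.65 ± 0.12) were higher and Gfra1 and Vgf lower. Among ATF4 targets (20, 0.102), Slc7a5 (-0.53 ± 0.11), Aldh1l2 (-0.65 ± 0.13) and Psat1 (-0.51 ± 0.13) were lower. Map7 and Map4 were higher and Map2 lower (-0.77 ± 0.15) among microtubule genes (37, 0.168), and Map2 was the 1 member past among pan-neuronal markers (18, 0.989). Of integrin and adhesion genes (30, 0.591), Itga8 (1.25 ± 0.21) and Tln2 (0.63 ± 0.18) were higher and Itga2 (-0.49 ± 0.14) and Itga6 (-0.46 ± 0.13) lower. With Schwann cell and fibroblast scores as covariates the log2 fold changes of Psat1, Itga6 and Mcm2 turned to 0.0217, 0.155 and 0.00617. Among respiratory chain genes (61, 0.387), Ndufb2 and Ndufab1 were higher and Ndufv3 lower. Hlf (1.28 ± 0.29) and Rorb were higher among clock genes (16, 0.622). Psma3 was higher and Psma6 lower among proteasome subunits (34, 0.387). Ddit4 was higher and Hk2 lower (-0.89 ± 0.22) among glycolysis and hypoxia genes (25, 0.929). Lists with 1 member past were YAP, TAZ and SRF targets (Tgfb2 higher, 18, 0.591), heat shock genes (Hspa1b higher, 19, 0.989) and extracellular matrix genes (Lamb2 higher, 34, 0.34). Others were intermediate filaments (Vim lower, 7, 0.34), cytosolic ribosomal proteins (Rps4l lower, 68, 0.387) and translation factors (Eif3c lower, 27, 0.0894). No member passed among actin genes (41, 0.594), transport motors (37, 0.0962), mitochondrially encoded mRNAs (13, 0.234) or NRF2 and antioxidant genes (21, 0.234). The same held for interferon response genes (22, 0.689), cholesterol synthesis genes (24, 0.387), autophagy and lysosome genes (26, 0.804), peptidergic nociceptor markers (9, 0.237), mechanoreceptor markers (9, 0.99) and nuclear-retained RNAs (7, 0.12). None passed among 2 skeletal muscle and 4 sex-linked genes, too few for a list test. The median, mean and test differed in sign for axon injury, glycolysis, heat shock, mechanoreceptor, pan-neuronal, satellite glia and spinal cord lists, none of which passed. When adjusted over the list alone, these lists had at most 5 members past in either direction. Of 12 fits that each left out 1 library, calls above ended in 10 for Itga2, Itga6, Ndufab1 and Nts, 9 for Ddit4, 8 for Ephb2, Map7, Psma3, Rps4l, Tln2 and Vgf, 7 for Map4, Psat1, Psma6 and Rorb, 5 for Ndufb2, 4 for Lamb2, 3 for Efna2 and 2 for Gfra1, Hk2 and Hspa1b.

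The number of genes past the threshold at 24 h rested on single libraries: it was 522 without 24 h replicate 7, 553 without control replicate 3, 621, 631, 642 and 649 without 24 h replicates 3 and 1 and control replicates 2 and 7, 1814 without 24 h replicate 2 and 432 without the 4 libraries apart on the first component. It was 2085 with library quality weights, 1826 with DESeq2 and 8 with Schwann cell and fibroblast marker scores as covariates, where the scores shared 77.9% of the variance of the group. The median absolute log2 fold change of the 1033 genes was 0.66 before and 0.64 with the covariates, while their median SE went from 0.148 to 0.282, so the lost calls do not tell whether cell content accounts for the change.

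**Figure D3:**
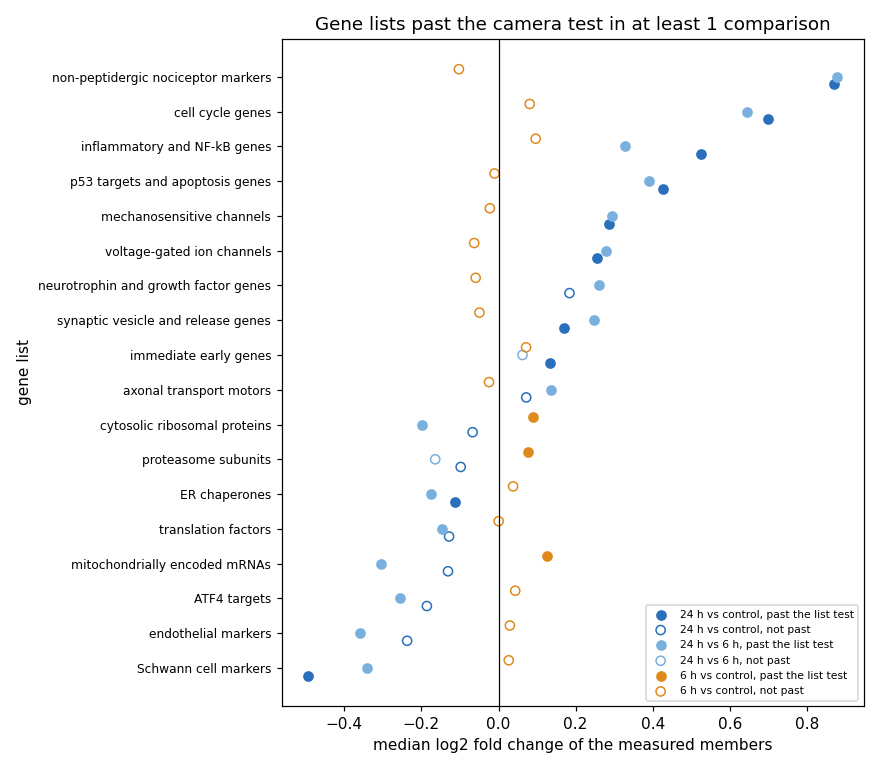
Median log2 fold change of the measured members of each gene list that passed camera in at least 1 comparison. Each point is a list in a comparison, filled where the list passed at the preset correlation. The non-peptidergic nociceptor markers lie at 0.87 for 24 h against control and 0.88 for 24 h against 6 h, and at -0.10 for 6 h against control.

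The comparison of 24 h with 6 h asked which transcripts differed between the later and the earlier time after the same cycles. Transcripts of the itch receptor Mrgprd, the pyruvate dehydrogenase kinase Pdk4 and the transcription factor Egr1 were higher at 24 h than at 6 h, and those of the haemoglobin gene Hbb-bt, the T cell receptor constant region Trbc2 and the Schwann cell receptor Erbb3 were lower. Mrgprd went from 991 ± 548 at 6 h to 3118 ± 1064 at 24 h (log2 fold change 1.79 ± 0.34, adjusted p = 0.00513), Pdk4 from 80.9 ± 33.7 to 506 ± 142 (2.75 ± 0.34, 0.000458) and Egr1 from 2139.7 ± 263 to 4826 ± 1109.9 (1.15 ± 0.14, 0.000458). Hbb-bt went from 588 ± 201 to 53.4 ± 20.5 (-3.46 ± 0.28, 1.69e-05), Trbc2 from 454 ± 204 to 87.6 ± 31 (-2.32 ± 0.29, 0.000527) and Erbb3 from 13970.5 ± 3079 to 8308 ± 584 (-0.72 ± 0.13, 0.00331). In each of these genes 6 of 6 24 h libraries lay on the same side of the 6 h mean.

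Of 15691 genes tested, 1215 passed, 641 higher and 574 lower at 24 h, with 195 and 106 of these over 2-fold. Among the largest increases were the ubiquitin-like modifier Ubd (7.32 ± 5.19 to 50.1 ± 14.7, 2.81 ± 0.38), Mrgpra3 (2.78 ± 0.46), Sp9 (2.65 ± 0.41), the glycosyltransferase Galnt5 (2.50 ± 0.37), Npffr1 (2.33 ± 0.32), Cxcl11 (2.30 ± 0.34), the matrix gene Cilp2 (71.9 ± 16.3 to 367 ± 139.6, 2.28 ± 0.24) and Pmaip1 (2.26 ± 0.29). Among the largest decreases were Sh2d1b1 (-3.29 ± 0.31), Hba-a1 (-3.00 ± 0.26), Hba-a2 (-2.82 ± 0.34), Dpm3 (-2.60 ± 0.65), the keratins Krt6b (-2.35 ± 0.42) and Krt16 (-2.05 ± 0.58) and Dmkn (-2.06 ± 0.26). Among 12 leave-one-out fits, the number in which a call above ended was 10 for Krt16 and 2 for Dpm3.

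Of the 43 lists, 9 rose and 7 fell at 24 h relative to 6 h, and 0 passed with an estimated correlation, where the adjusted p was 0.339 for non-peptidergic nociceptor, mechanosensitive channel, p53, ER chaperone and Schwann cell lists and 0.743 for the other 11. Of 12 non-peptidergic nociceptor markers, 5 were higher, or 8 adjusted over the list alone (median 0.88, adjusted p = 3.71e-06), namely Mrgprd, Mrgpra3, Mrgprb5 (3.12 ± 0.46), Mrgprx1 (2382 ± 1409.8 to 7957 ± 4073, 1.90 ± 0.48) and Nppb. Of 25 p53 targets and apoptosis genes, 8 were higher, or 13 adjusted over the list alone (median 0.39, adjusted p = 3.06e-05), including Mdm2, the ubiquitin ligase of p53 (52 ± 8.51 to 104 ± 25.1, 0.97 ± 0.18), and the survival gene Bcl2 (0.50 ± 0.12). Of 21 mechanosensitive channels, 5 were higher, or 7 adjusted over the list alone (median 0.29, adjusted p = 0.00259), namely Asic2 (0.81 ± 0.16), Trpc6 (1.44 ± 0.38), Trpc1 (0.40 ± 0.10), Trpc3 and the capsaicin receptor Trpv1 (209 ± 70.5 to 370.5 ± 88.4, 0.85 ± 0.22). Of 41 voltage-gated channel genes, 5 were higher and 1 lower, or 10 and 2 adjusted over the list alone (median 0.28, adjusted p = 0.00475), with Scn2b (0.82 ± 0.16), Cacna1c (0.66 ± 0.16), Kcnc4 (0.41 ± 0.11), Cacna2d1 (0.63 ± 0.14) and Kcnb1 higher and Cacna2d3 lower. Of 32 synaptic genes, 6 were higher, or 7 and 1 lower adjusted over the list alone (median 0.25, adjusted p = 0.00326), including Unc13a (0.52 ± 0.11) and Nrxn2 (0.64 ± 0.13). The growth factor list rose (4 higher and 1 lower of 19, or 6 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.0376), with Igf1 (0.94 ± 0.17), Lifr (0.70 ± 0.11), Il6st (0.38 ± 0.09) and the receptor Ntrk2 (0.52 ± 0.14) higher and Gfra1 lower. The inflammatory list rose (23 measured, median 0.33, adjusted p = 0.016), with Ptgs2 (1.34 ± 0.27) and Icam1 (1.13 ± 0.24) higher and Cxcl12 lower, or 5 and 2 adjusted over the list alone. The cell cycle list rose (30 measured, median 0.64, adjusted p = 0.016), with the kinesin Cenpe (1.58 ± 0.41) and cyclin Ccnb1 (0.99 ± 0.27) higher and Mcm2 lower, both over all genes and adjusted over the list alone. The axonal transport motor list rose (37 measured, median 0.14, adjusted p = 0.0179), though the member past was the dynactin subunit Dctn6, which was lower (-0.43 ± 0.12), and 0 passed adjusted over the list alone. Of 12 fits that each left out 1 library, calls above ended in 10 for Cxcl12 and Dctn6, 9 for Trpc3, 8 for Ccnb1 and Nppb, 7 for Gfra1 and Trpv1, 6 for Cenpe and Kcnb1, 5 for Cacna2d3 and Trpc6, 4 for Mrgprx1 and Trpc1, 3 for Kcnc4 and Ntrk2 and 1 for Cacna1c.

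Among the lists that fell from 6 h to 24 h, the 68 cytosolic ribosomal protein genes had a median of -0.20 (adjusted p = 0.00466) with Rps4l, typed as a transcribed processed pseudogene, lower (-0.51 ± 0.12), also adjusted over the list alone. The 13 mitochondrially encoded mRNAs had a median of -0.31 (adjusted p = 0.00964, ended with quantile normalization at 0.0638) with 0 members past on either adjustment, and mt-Nd2 measured 74447 ± 13207 and 58462 ± 14167. ER chaperones (18 measured, median -0.18, adjusted p = 0.00712) included Sdf2l1 (-0.56 ± 0.13), the member past on both adjustments. ATF4 targets (20 measured, median -0.26, adjusted p = 0.0273) had the serine synthesis enzymes Phgdh (1229.7 ± 126 to 809 ± 239, -0.64 ± 0.15) and Psat1 (-0.56 ± 0.12), Aldh1l2 (-0.61 ± 0.12) and Slc7a5 (-0.49 ± 0.11) lower, or 4 lower and 1 higher adjusted over the list alone. Translation factors (27 measured, median -0.15, adjusted p = 0.016) had Eif3c lower (-0.40 ± 0.07) on both adjustments. Schwann cell markers (14 measured, median -0.34, adjusted p = 0.00326) had 6 lower and 1 higher, the myelin gene Mbp (0.47 ± 0.14), on both adjustments. Endothelial markers (7 measured, median -0.36, adjusted p = 0.0228) had Cldn5 lower (-2.07 ± 0.41) on both adjustments. Mbp, Cldn5, Nppb, Trpc3, Kcnb1 and Cacna2d3 were named after their values in this comparison were seen. Without the 4 libraries apart on the first component, the calls of ribosomal protein, ATF4, inflammatory, growth factor, translation factor and endothelial lists ended (adjusted p of 0.218, or 0.256 for ATF4 targets), as did that of cell cycle genes (0.630). Among 12 leave-one-out fits, the number in which a call above ended was 11 for Mbp.

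The number of genes past the threshold was 627 without 24 h replicate 7, 716 without 24 h replicate 1, 799 without 24 h replicate 3, 2398 without 24 h replicate 2 and 627 without the 4 libraries apart on the first component. It was 2791 with library quality weights, 2019 with DESeq2 and 565 with Schwann cell and fibroblast scores as covariates, of which 72.6% were higher at 24 h, against 52.8% without covariates. Of the 1215 genes, only 258 kept their call and direction with the covariates. The variance that the scores share with the group was measured only for 24 h against control.

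The comparison of 6 h with control asked which transcripts differed soon after the compression cycles. No single gene passed. The libraries of the transcription factor Egr1, the apoptosis gene Pmaip1, the itch receptor Mrgprd and the prostaglandin synthase Ptgs2 overlapped between 6 h and control, and the globin gene Hbb-bt measured 683 ± 427 in control and 588 ± 202 at 6 h (log2 fold change -0.08 ± 0.34). Lists of ribosomal protein, mitochondrially encoded and proteasome transcripts passed as higher only at the preset correlation, with 0 members past and medians of 0.09, 0.13 and 0.08. With an estimated correlation the adjusted p was 0.986 for each, and the mitochondrially encoded list no longer passed with quantile normalization (0.0790).

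Of 15655 genes tested with limma, 0 passed, the smallest adjusted p was 1.00 and 337 had an unadjusted p under 0.05, where chance gives 783. DESeq2 and edgeR also called 0 genes, with 356 and 343 at an unadjusted p under 0.05. With the replicate number as a block, which pairs these libraries, limma again called 0, with 1196 at an unadjusted p under 0.05, and edgeR 0 with 1236. The genes with the smallest p were Acap2 (54.6 ± 4.97 to 35 ± 5.6, -0.64 ± 0.15), Zfp991 (-0.31 ± 0.08), Gprin3 (-0.45 ± 0.12), the potassium channel Kcna1 (334 ± 57.4 to 238 ± 49.9, -0.50 ± 0.15), Asmt (0.47 ± 0.15), the respiratory chain subunit Ndufa2 (2841 ± 218 to 3385 ± 356, 0.25 ± 0.08), Mut (-0.18 ± 0.06), Zscan26 (-0.32 ± 0.11), Klhl28 (-0.22 ± 0.07) and Coq9 (0.31 ± 0.10), and none passed.

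Of the 43 lists, 3 rose at 6 h and 0 fell, with 0 members past on either adjustment, over all genes or adjusted over the list alone, in any list. These were the 71 cytosolic ribosomal proteins (adjusted p = 9.88e-05), the 13 mitochondrially encoded mRNAs (0.0105, ended with quantile normalization at 0.0790 and without the 4 libraries apart on the first component at 0.189) and 33 proteasome subunits (0.0156), each with an adjusted p = 0.986 with an estimated correlation. Rplp0 measured 979 ± 89.1 in control and 1126 ± 125 at 6 h (0.20 ± 0.09), mt-Co2 54526 ± 13468 and 62486 ± 12721 (0.21 ± 0.16) and Psmd3 2709.8 ± 226 and 3019 ± 326 (0.15 ± 0.08). With the replicate block, 12 lists passed. The 9 added were immediate early genes (adjusted p = 0.0334), respiratory chain (0.0274), inflammatory (0.0116), interferon response (0.018), cell cycle (0.0116) and fibroblast genes (0.0334), which were higher, and synaptic (0.018), voltage-gated channel (0.0334) and mechanoreceptor genes (0.018), which were lower. None of the 12 passed with an estimated correlation, where the smallest adjusted p was 0.202. Schwann cell markers (adjusted p = 0.782, median 0.03) and non-peptidergic nociceptor markers (0.776, median -0.10) did not pass, with or without the block.

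Across 16346 genes, which are not independent replicates, log2 fold changes from control at 6 h and at 24 h had a Pearson correlation of 0.210. Both use the same controls, and unchanged groups simulated against those controls gave a median of 0.483 (-0.0204 to 0.791 in 100 draws). The covariance was 0.0174, against 0.0310 simulated, a difference of -0.0136. That simulation took no account of the pairing of 6 h and control libraries. When the pairs were kept, it gave a median correlation of 0.412 (0.0760 to 0.692 in 99 of 100 draws, with 1 draw undefined) and a median covariance of 0.0174, a difference of -0.0000284. With the controls split 3 and 3 between the times, the median correlation over 20 splits was -0.0649 (-0.388 to 0.0768), where 6 h libraries paired with the controls of the other side can lower it. With 6 h libraries kept only on the side of their paired controls it was -0.00671 (-0.147 to 0.0716). Both comparisons at 24 h use the same 24 h libraries. Among 15453 genes tested in both, 412 of the 521 higher against control were among the 641 higher against 6 h, where independent lists share 21.6. Groups simulated without effects shared 0, a reference that leaves out the effects. For lower genes, 368 of 507 were among 564, against 18.5 for independent lists and 0 simulated. With the 24 h libraries split 3 and 3 between the comparisons, the median overlaps were 27.5 higher and 38.5 lower genes, where independent lists share 1.18 and 1.47. That split leaves the pairing of 6 h and control libraries in both comparisons. With no replicate number of control and 6 h shared either, the median overlaps over 400 splits were 0 higher (0 to 75) and 2 lower genes (0 to 27). With 3 libraries per group, 1 or both comparisons called 0 higher genes in 209 of these splits and 0 lower genes in 110. These counts therefore cannot tell how much of the overlap is shared deviation. In the same 400 splits the log2 fold changes of the 2 comparisons had a median correlation of 0.512 (0.143 to 0.721). It was thus positive in each split, without a shared library or a shared replicate number of control and 6 h.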

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

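The tests of library scaling, time in culture, neuron share, Schwann cell share and Schwann cell and fibroblast content were chosen after the result was seen. Values of 552 groups of 6 libraries were examined for a library far from the others, and 42 had one, where chance gives about 1 in 20, or 27.6. Control replicate 2, 6 h replicate 2 and 24 h replicate 2 held 6 of these each and 6 h replicate 3 held 5.

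Among the control libraries, 14 values lay apart from those of the other 5 replicates, in normalized counts unless another unit is given. In control replicate 1 this was mt-Nd2 at 88702 (others 56932 to 66857), Acap2 at 45.3 (others 54.1 to 59) and Zfp991 at 333 (others 380.2 to 399). The same library had the percent of reads in mitochondrially encoded genes at 6.7 (others 4.26 to 5.1). In control replicate 2 this was Pdk4 at 7.51 (others 64.7 to 145), Npffr1 at 9.66 (others 51.1 to 87) and Nts at 7424 (others 3768 to 4339). The same library had Notch3 at 498 (others 1111 to 1354), Galnt5 at 6.44 (others 18.1 to 24.6) and Coq9 at 136 (others 168 to 186). In control replicate 3 this was Glul at 1688 (others 2172 to 2483), Ntrk2 at 270.2 (others 393 to 479) and the percent of reads in pseudogenes at 17.7 (others 15.3 to 16.2). In control replicate 4 this was Foxd3 at 1829 (others 2186 to 2375).

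Among the 6 h libraries, 17 values lay apart from those of the other 5 replicates, in normalized counts unless another unit is given. In 6 h replicate 1 this was Ndufb2 at 134 (others 199 to 244). In 6 h replicate 2 this was Nkx2-9 at 2.79 (others 12.9 to 29.4), Pdk4 at 20.5 (others 64.2 to 111) and Sp9 at 1.86 (others 14.2 to 21.4). The same library had Npffr1 at 16.8 (others 46.4 to 78.5), Slc7a5 at 15408 (others 17570.2 to 18759) and Cavin1 at 5981 (others 7742 to 8580.0). In 6 h replicate 3 this was Cxcl11 at 6.42 (others 25.1 to 54), Rps4l at 2628 (others 1858 to 2077) and Glul at 1631 (others 2189.7 to 2436). The same library had Ntrk2 at 228 (others 369 to 420.4) and the percent of reads in pseudogenes at 17.3 (others 15.7 to 16.2). In 6 h replicate 4 this was Hyou1 at 88 (others 134 to 157), Kdm5d at 8.52 (others 40.0 to 76.5) and Cilp2 at 41.6 (others 67.5 to 88.4). The same library had the percent of reads in transcripts without a gene name at 11.1 (others 4.06 to 6.12). In 6 h replicate 7 this was Myh8 at 3.98 (others 11.2 to 18.6).

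Among the 24 h libraries, 11 values lay apart from those of the other 5 replicates, in normalized counts unless another unit is given. In 24 h replicate 1 this was Fas at 20.0 (others 42.6 to 59.9) and Srxn1 at 11419 (others 16117 to 18786). In 24 h replicate 2 this was Npffr1 at 127 (others 244 to 356), Vim at 3672 (others 2162 to 2326) and Galnt5 at 43.7 (others 71 to 92.9). The same library had Kcna1 at 106 (others 264 to 391), Psmd3 at 3692 (others 1887 to 2323) and Foxd3 at 1920.3 (others 975 to 1159). In 24 h replicate 4 this was total reads at 18759966 (others 19782769 to 20208926). In 24 h replicate 7 this was Dpm3 at 0 (others 8.01 to 25.6). In 24 h replicate 8 this was Psma6 at 889 (others 671 to 714).

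Of the 93 named genes past the threshold between 24 h and control, 82 also differed between 24 h and 6 h. This tests whether the change from control differs between the times, and over all genes 1215 did. Both comparisons use the same 24 h libraries and these genes were picked by the first, so the 82 are not independent support. Over all genes tested in both, 412 of 521 higher and 368 of 507 lower against control were also called against 6 h. 49 of the 82 were higher at 24 h than at 6 h. The log2 differences were Mrgprb5 3.12, Mrgpra3 2.78, Pdk4 2.75, Sp9 2.65, Pnliprp2 2.43, Npffr1 2.33, Cxcl11 2.30, Mrgpra2b 2.27, Pmaip1 2.26, Hist1h1b 2.11, H2-Q6 2.11, Chrm1 2.10, Nkx2-9 1.97 and Mrgprd 1.79. Next came Clca2 1.72, Fas 1.62, Ptgs2 1.34, Notch3 1.32, Lyz2 1.22, Hlf 1.21, Btg2 1.18, Nppb 1.17, Egr1 1.15, Icam1 1.13, Itga8 1.11, Efnb3 1.07, Igf1 0.94 and Sema4d 0.92. Then followed Rorb 0.87, Junb 0.86, Scn2b 0.82, Asic2 0.81, Tgfb2 0.76, Lamb2 0.74, Lifr 0.70, Ndufb2 0.68, Nrxn2 0.64, Bbc3 0.64, Tln2 0.60, Map4 0.60, Syt2 0.57 and Hspa1b 0.52. Smaller differences were Unc13a 0.52, Psma3 0.48, Nrxn3 0.47, Trpc3 0.46, Kcnc4 0.41, Trpc1 0.40 and Plk2 0.39. The other 33 were lower at 24 h. Here the log2 differences were Hbb-bt -3.46, Sh2d1b1 -3.29, Hba-a1 -3.00, Hba-a2 -2.82, Dpm3 -2.60, Krt6b -2.35, Trbc2 -2.32, Tmprss11b -2.07, Dmkn -2.06, Trbc1 -2.03, Shisal2a -2.01, Nmu -1.80, Arg1 -1.22 and Olig2 -1.09. Further decreases were Cxcl12 -0.95, Hk2 -0.80, Gfra1 -0.77, Dusp5 -0.72, Erbb3 -0.72, Cacna2d3 -0.72, Vim -0.71, Nts -0.68, Map2 -0.63, Ndufv3 -0.62, Aldh1l2 -0.61, Psat1 -0.56, Efna2 -0.55 and Ephb2 -0.53. The smaller decreases were Rps4l -0.51, Slc7a5 -0.49, Cdh19 -0.47, Mcm2 -0.45 and Eif3c -0.40.

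Transcripts that matched no gene in the annotation were outside the comparisons of genes. Tested on their own with limma, 53 passed between 24 h and control (35 higher and 18 lower at 24 h, of 1293 tested) and 57 between 24 h and 6 h (38 higher and 19 lower, of 1301), and 0 passed between 6 h and control.

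The 1033 genes that differed between 24 h and control argue against chance, since of 100 splits of the 12 libraries, drawn from 462, 1 gave as many, the real split, and the highest other gave 117. Of these genes, 98.0% kept their call and direction with quantile normalization or TMM, whichever was lower. This argues against the choice among these scalings as the whole cause. Each of them brings the libraries to a common level, so a shift shared by most genes was not tested. Open is time in culture, since 0 control libraries have a stated extraction time. Schwann cell and fibroblast content is open too, since its scores shared 77.9% of the variance of the group. So is a difference between sets of cultures, since replicate numbers did not pair each 24 h library with a control (2 of 6 closest to their own number). The splits cannot test such a difference, and other splits of the 6 h and control libraries called up to 1580 genes. With both scores in the fit 8 genes passed. The median SE of the called genes went from 0.148 to 0.282 while their median absolute log2 fold change went from 0.66 to 0.64. Of the 1033, 37 turned direction. Compression, which the design names, cannot be told apart from these and was not tested separately.

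The higher non-peptidergic nociceptor markers at 24 h may involve reads shared among the Mrgpr genes, and this stays open. The 8 other members had a median log2 fold change of 0.38. Tested as a list with limma camera they gave p = 0.00292 at the preset correlation and 0.101 with an estimated correlation. At the preset correlation this met the rule set before for arguing against shared reads, a median of at least 0.2 with p under 0.05. The median lay above 0.2 by less than the SD of the members (0.490), a condition that was not part of that rule. Of the 8, 1 passed, Nppb. A larger share of neurons would raise the pan-neuronal markers alike. These had a median of 0.0441 with an SD of 0.283 over their 18 members, against 0.87 for the nociceptor list, so they did not rise as a set. The verdict on the gap between the lists depends on the bound. An earlier bound, 3 times the standard error of the difference (0.286, from the spread of both lists), was not met. The gap passed only a bound of 2 SD of the pan-neuronal members, set after these values were seen. A larger share of neurons is therefore not excluded. A difference between kinds of neurons and a change within them stay open too, as do time in culture and a difference between sets of cultures.

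For the lower Schwann cell markers at 24 h, a smaller share of Schwann cells would lower all members alike only if other cells did not make them. Of 16 members, 4 lay more than 3 standard errors from the list median of -0.49, so the fall was not uniform. Which cells made each marker was not tested, so this does not decide on a smaller share. A smaller share, alone or together with a change within the cells, stays open. So do time in culture and a difference between sets of cultures.

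For 24 h against 6 h, 1 of 100 splits, drawn from 462, gave as many genes as the real split (1215), and the highest other gave 885. This argues only against a random grouping of these libraries as the source of the count. The splits cannot test a difference between sets of cultures or time in culture, which stay open here too. For 6 h against control, 100 of 100 splits gave at least as many as the real 0, which any split must, so this count tests nothing. The highest other gave 1580, which points to a structure of the samples that crosses the groups. The replicate numbers pair these 2 groups. Among the 32 splits that part all 6 pairs, with the replicate block, the real split had 0 genes past the threshold and the highest other 12. At an unadjusted p under 0.05 the real split had 1196, 6 of the 32 had as many and the highest other had 1448.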

How the results depend on the processing

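The tests without the 4 libraries apart on the first component, with Schwann cell and fibroblast scores as covariates, on protein-coding genes, on single transcripts, with the length correction, of the correlation with paired 6 h libraries, of overlaps without shared replicate numbers, of lists with both the replicate block and an estimated correlation, and of lists under other scalings were chosen after the data were seen.

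The 1033 genes past the threshold between 24 h and control stayed within 1.5 times that number with pseudocounts of 0.5 and 5, both filters, quantile normalization, TMM, all 18 libraries, the replicate block and edgeR (731 to 1380). They became 2085 with library quality weights and 1826 with DESeq2, and the cause was not tested. Leaving out a library gave 522 (without 24 h replicate 7) to 1814 (without 24 h replicate 2). Without the 4 libraries apart on the first component, with fewer samples, there were 432. With the covariates there were 8, where the SE of called genes rose from 0.148 to 0.282. The 1215 genes between 24 h and 6 h stayed within 1.5 times under the same settings (963 to 1542). They became 2791 with library quality weights and 2019 with DESeq2, cause not tested, 627 without the 4 libraries and 565 with the covariates, and leaving out a library gave 627 (without 24 h replicate 7) to 2398 (without 24 h replicate 2). With the covariates, 258 of the 1215 kept their call and direction. DESeq2 gave no adjusted p for 305 and 307 genes. Between 6 h and control 0 genes passed with limma, edgeR and DESeq2 under each setting, where leaving out a library gave 196 to 635 at an unadjusted p under 0.05.

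Among named genes, 53 of 93 calls between 24 h and control and 62 of 102 between 24 h and 6 h held in each fit without 1 library. In both, 1 more gene, Mrgprb5, was not tested in 6 fits and held in the other 6. With the covariates, 37 of the 1033 called genes turned direction between 24 h and control and 14 of the 1215 between 24 h and 6 h. Of named genes 3 reversed, all between 24 h and control, Psat1 (log2 fold change 0.0217), Itga6 (0.155) and Mcm2 (0.00617), and the cause was not tested.

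Gene lists past the threshold were 10, 16 and 3 for 24 h against control, 24 h against 6 h and 6 h against control, and 0 in each with an estimated correlation, with or without the replicate block, since the estimate widens the test of lists whose members vary together. With the block at the preset correlation they were 10, 21 and 12. Replicate numbers were taken to pair groups where the deviations of each pair from their group means correlated above 0.1. This held for 6 h and control (lowest 0.112, 4 of 6 closest to their own number). It did not hold for 24 h and control (lowest -0.125, median 0.118, 2 of 6) or 24 h and 6 h (lowest -0.0346, median 0.182, 3 of 6). By this rule only the 12 is a paired result, and pairing of part of the 24 h libraries is not excluded. Without the 4 libraries the lists past the threshold were 7, 10 and 3, with quantile normalization 9, 17 and 2 and with TMM 10, 18 and 3. With the replicate block and a correction for transcript length 10 passed between 6 h and control. The ribosomal protein transcripts were short (median length 639.5, against 1336 for all genes). After the correction 73.5% of their median log2 fold change was kept (0.09 to 0.07, camera adjusted p = 0.0198 at the preset correlation). Length as corrected here, by a smooth trend per library, may account for part but not the whole. Whether such a trend corrects the shortest transcripts in full was not tested.

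The correlation across genes between the changes at 6 h and at 24 h reversed from 0.210 to a median of -0.0649 when the controls were split 3 and 3 (-0.388 to 0.0768), and to -0.00671 (-0.147 to 0.0716) when the 6 h libraries were kept only with their paired controls. Shared controls alone raise the correlation, and the first split, which ignores the pairs, can lower it.

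Depth and the spread between libraries limit small changes. In simulated data of the same depth, 2.00% to 5.60% of genes changed 1.25-fold were recovered, 26.0% to 34.0% at 1.5-fold, 63.6% to 70.4% at 2-fold and 91.2% to 93.2% at 4-fold, with 3.52% to 3.81% false calls. A simulated list of shifted genes passed camera at the preset correlation in 5 of 5 draws per comparison. A list of unchanged genes also passed, at an unadjusted p under 0.05, in 1 of 5 draws for 24 h against control and in 0 of 5 for the others. Genes were simulated independently, so these draws do not test the preset correlation. The simulated libraries also had no pairs and no structure shared among samples. The shares recovered and false therefore need not hold for the real libraries, where other splits of 6 h and control libraries called up to 1580 genes.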

Other observations

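All tests here were chosen after the data were seen. Replication-dependent histone genes were higher at 24 h than in control in 5 of 33 measured members (median log2 fold change 0.20, camera adjusted p = 0.00339, and 0.391 with an estimated correlation) and in 3 of 34 against 6 h (0.21, 0.00878, and 0.391). Between 6 h and control 0 of 30 passed (0.03, 0.576). The libraries were of polyadenylated RNA, so these counts need not follow the amount of histone transcripts without a poly(A) tail. Hist1h1b was at 2.1 and 0 in control replicates 2 and 3, against 15.7 to 29.5 in the other controls. Without the 4 libraries apart on the first component, the histone list had 4 of 33 members higher against control (0.28, adjusted p = 0.00000401, and 0.151 with an estimated correlation) and 4 of 33 against 6 h (0.26, 0.000196, and 0.151). Keratin genes were lower in 2 of 13 members against control (-0.33, 0.00883, and 0.141 with an estimated correlation) and 3 of 15 against 6 h (-0.36, 0.0171, and 0.141), and 0 of 17 passed between 6 h and control (-0.00, 0.833). Without the 4 libraries the keratin list no longer passed against control (-0.38, adjusted p = 0.105) or against 6 h (-0.19, 0.118), with an adjusted p = 0.151 with an estimated correlation in both.

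Cell cycle genes averaged 6.72 and 7.30 log2 units in control replicates 2 and 3 and 7.04 and 7.69 in 6 h replicates 2 and 3, against 8.37 to 8.95 in the other 14 libraries. These 4 libraries are those that lay apart on the first principal component.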
